A study of Mus musculus with 4 samples.

How the data were processed

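The series holds 4 single-cell libraries from C57BL/6 mice that carried CT2A, a mouse glioma line, in the brain. Gene expression (GEX) and B cell receptor (BCR) libraries were made from the skull bone marrow and from the brain tumor, 1 library for each tissue and assay, per the labels. The mice were 8 weeks old at injection and the tissues were taken 14 days later. Cells were enriched on magnets for PNA binding and sorted as live, DAPI-negative cells. PNA is the usual abbreviation of peanut agglutinin, a lectin used to enrich germinal centre B cells. The libraries were 10x Genomics Chromium libraries read on an Illumina NextSeq, per the labels' protocols.

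The analysis used 1 table, the receptor contigs of the BCR library that GEO records under skull bone marrow. The other 3 libraries were not analysed here. The record and the table name different tissues: all 60 rows of the table carry 1 sample name that contains the word brain and 0 rows carry one that contains skull. No value in the table decides which name is right. The library is therefore called the library labelled skull bone marrow, and no statement here rests on its tissue.

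Cell Ranger 9.0.1, bcl2fastq and the mm10 build are named in the submitters' processing notes. The V(D)J reference is not given in the sources used here. Each row of the authors' table is an assembled receptor contig with its V, D, J and constant gene, the nucleotide sequence of each framework and complementarity-determining region (CDR), a clonotype name, and 2 numbers. These numbers are raw counts as deposited by the authors, of the unique molecular identifiers (UMIs) and of the reads behind the contig, with no normalization. Reads are PCR copies, so UMIs were used wherever amounts were described. All 60 contigs were marked as productive, full length, of high confidence and in a cell, so the table was already filtered when it was deposited.

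A cell is a barcode with at least 1 contig. Each barcode had at most 1 heavy and 1 light contig, so no choice between contigs was needed. No doublet caller was run. A doublet of 2 B cells with all chains recovered would show as a barcode with more than 1 heavy or light contig, of which there were 0. Doublets with a cell that is not a B cell, or with chains lost, would not show this way. Whether barcodes with several contigs of a class had been removed before deposit is not given in the sources used here. Clonotypes are those of the authors' table. Shares of cells are given with exact Clopper-Pearson 95% intervals. Where a class was not seen, the limit is 3 counts of the total. An interval had been planned for the share of cells in clonotypes of 2 or more, but none is given, since cells of 1 clone are not independent draws. Medians are given with the range over cells. These intervals and limits cover counting error only. With 1 library there is no replicate, cells are not replicates, and no p-value was computed. With 28 heavy and 32 light chains, a class seen in 0 cells could still make up to 10.7% of heavy or 9.38% of light chains by that limit, which is one-sided. The two-sided exact intervals, which the figure of constant genes draws, reach 12.3% and 10.9% for the same zeros.

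Germline V genes were taken from the GENCODE M21 transcripts on GRCm38, the assembly that mm10 names, which derives from C57BL/6J. Its annotation held the V gene named for each of the 60 contigs, 18 heavy and 20 light V genes in all. Framework 1 to framework 3 of each chain, which ends before the CDR3, was aligned to the named V gene with Biopython 1.88 (match 1, mismatch -2, gap opening -6, gap extension -1, free ends on the germline side), and differing bases were counted. No alignment had a gap. The named gene was also the best match for all 60 chains, and 0 chains tied with another V gene. The count was tested on simulated data: in 200 germline sequences of these V genes with up to 15 substitutions, the exact number was counted in 200. V positions are counted from 1 at the first base of framework 1, and CDR3 positions from 1 at the first base of the cysteine codon that opens it. CDR3 lengths include that cysteine and the closing tryptophan or phenylalanine, as in the table. Hotspots of AID, the enzyme that starts somatic hypermutation, were the C of WRC and the G of GYW motifs in the germline gene. Gene coordinates are those of GENCODE M21 on GRCm38, 1-based. Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3 were used.

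The descriptions, their alternatives and these gene lists were fixed before the data were examined: unswitched constant genes (IGHM, IGHD), switched constant genes (IGHG1, IGHG2A, IGHG2B, IGHG2C, IGHG3, IGHA, IGHE), heavy V genes of phosphatidylcholine-binding B-1 cells (IGHV11-2, IGHV12-3), of anti-phosphorylcholine antibodies (IGHV7-1) and of the response to the hapten NP (IGHV1-72), the IGHV1 family, the IGHV5 and IGHV2 families nearest the D genes, the lambda constant genes, and T cell receptor chains as a sign of other lymphocytes. IGHG2A has no gene in the GRCm38 annotation used. The text names each heavy constant gene and light class, each clonotype of 2 or more cells, up to 10 heavy and 10 light V genes among those with at least 2 cells, and the members of the lists. Cells outside this rule, such as the most mutated cell and the pair of similar receptors, were chosen after their values were seen. Markers of cell types had been fixed for an expression matrix and were not used. The alternatives were a minimum of 3 UMIs per contig, leaving out barcodes with several contigs of a class, counting clonotypes in place of cells, keeping only cells with both chains, using contigs whether productive or not, own clonotype definitions from the heavy chain, the best-matching V gene, and a V part without framework 1.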

Results

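The receptor library labelled skull bone marrow held 60 contigs in 33 cells, 28 heavy and 32 light chains. They rested on 1948 UMIs and 1582984 reads, or 813 reads per UMI, and single contigs had between 1 and 272 UMIs. The rows of its table name the brain, so the tissue is open. The series was designed to set B cells of the skull marrow beside those of the CT2A tumor in the brain, by expression and by receptor sequence. That comparison could not be made from 1 receptor library. What follows describes the receptors of these 33 PNA-selected cells. There were no replicates, so the values describe this library and intervals cover counting error only.

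A heavy and a light chain were both recovered in 27 of the 33 cells, or 81.8% (exact Clopper-Pearson 95% interval 64.5 to 93.0%). Another 5 cells had only a light chain and 1 cell had only a heavy chain. No cell had more than 1 heavy or more than 1 light chain, which allows a share of up to 9.09%. T cell receptor chains made up 0 of the 60 contigs. A library enriched for B cell receptors would not hold them whatever cells were sorted, so this says nothing about other lymphocytes.

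The heavy chains were almost entirely unswitched. IgM, encoded by IGHM (chromosome 12, 113418558 to 113422730), was the constant region in 23 of 28 cells, or 82.1% (63.1 to 93.9%). IgD, made from the neighbouring IGHD (chromosome 12, 113406604 to 113416324) by alternative splicing of the same transcript, was seen in 3 cells, or 10.7% (2.27 to 28.2%). Together IgM and IgD covered 26 of 28 cells, or 92.9% (76.5 to 99.1%). The remaining 2 cells, 7.14% (0.877 to 23.5%), had switched to IgG. One carried IGHG2C (chromosome 12, 113285325 to 113288932) and the other IGHG3 (chromosome 12, 113356224 to 113361232). IGHG1, IGHG2B, IGHA and IGHE were each seen in 0 of 28 cells, which allows up to 10.7% for each. IGHG2A was also not seen, but C57BL/6 mice carry IGHG2C in its place, so that zero is not a measurement.

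Among light chains, kappa made up 25 of 32 cells, or 78.1% (60.0 to 90.7%), and lambda 7 of 32, or 21.9% (9.28 to 40.0%). The lambda chains were mostly of the lambda 2 type: 6 joined IGLV2 (chromosome 16, 19260401 to 19260859) to IGLJ2 and IGLC2, and 1 joined IGLV1 (chromosome 16, 19085017 to 19085500) to IGLJ1 and IGLC1. IGLV2 was thus 18.8% of light chains (7.21 to 36.4%) and 6 of 7 lambda chains, or 85.7% (42.1 to 99.6%). IGLC3 was seen in 0 of 32 cells, which allows up to 9.38%. No kappa cell carried a lambda contig (0 of 25). Since no barcode held more than 1 light contig, that zero follows and is not a separate measurement. The 6 lambda 2 chains had 1 and the same CDR3, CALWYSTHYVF, down to the nucleotide, but the 5 of these cells with a heavy chain had 5 different heavy CDR3s on 4 V genes.

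**Figure D1:**
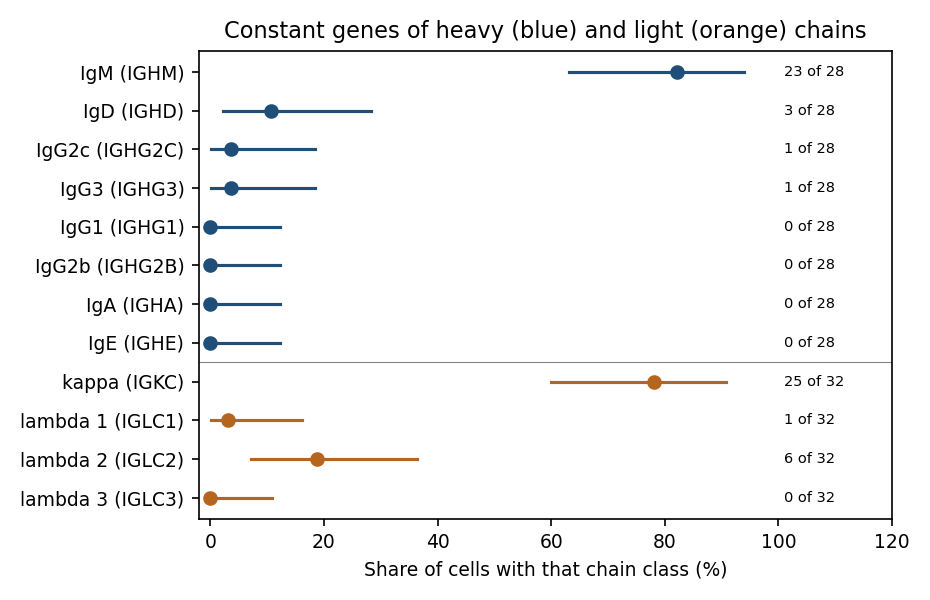
Share of cells with each constant gene, in percent of the 28 cells with a heavy chain (blue) or the 32 cells with a light chain (orange). Points are shares and lines exact Clopper-Pearson 95% intervals, with the counts of cells at the right. IgM stood at 82.1%, kappa at 78.1% and lambda 2 at 18.8%.

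The heavy chains drew on 18 of the 113 V genes annotated in the locus, and used both its ends. The IGHV1 family (J558), the largest in the mouse, gave 18 of 28 chains, or 64.3% (44.1 to 81.4%). It holds 46.9% of the annotated V genes, a value within that interval. IGHV5, a family close to the D genes, gave 5 chains, or 17.9% (6.06 to 36.9%), against 8.85% of the annotated genes. IGHV2, also close to the D genes, lay the other way, with 1 chain, or 3.57% (0.0904 to 18.3%), against 7.96%. Both annotated shares lie within the intervals. Together these D-proximal families made up 21.4% (8.30 to 41.0%). IGHV6 gave 3 chains and IGHV13 gave 1. The most used gene was IGHV5-17 (chromosome 12, 113859149 to 113859670), with 4 cells or 14.3% (4.03 to 32.7%). IGHV1-9 (chromosome 12, 114583569 to 114584002) followed with 3 cells. IGHV1-19, IGHV1-26, IGHV1-64, IGHV1-76 and IGHV6-3 had 2 cells each. The 4 IGHV5-17 cells carried 4 different CDR3s, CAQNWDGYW, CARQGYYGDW, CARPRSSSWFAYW and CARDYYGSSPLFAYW. None of the fixed lists of antigen-associated V genes was represented. IGHV11-2 and IGHV12-3, typical of phosphatidylcholine-binding B-1 cells, were in 0 of 28 cells, as were IGHV7-1 and IGHV1-72, and each of these zeros allows up to 10.7%.

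**Figure D2:**
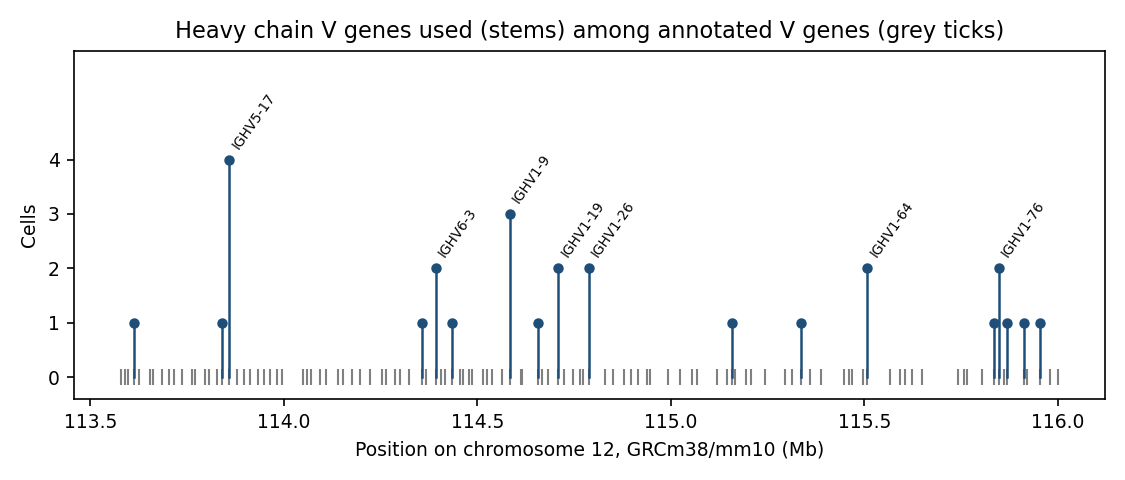
Position of heavy chain V genes on chromosome 12 (GRCm38, in megabases) against the number of cells that used each. Grey ticks are the 113 annotated V genes and blue stems the 18 used, named where at least 2 cells used them. IGHV5-17 had 4 cells and IGHV1-9 had 3, and used genes lay at both ends of the locus.

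Kappa chains used 18 V genes in the 25 kappa cells. IGKV1 was the most used kappa family with 6 cells, or 24.0% of kappa chains (9.36 to 45.1%), against 10.0% of the 100 annotated kappa V genes. IGKV4, the largest annotated family with 26.0% of the genes, gave 2 chains, or 8.00% (0.984 to 26.0%). The single genes seen more than once were IGKV1-117 with 3 cells, and IGKV1-110, IGKV10-96, IGKV12-41, IGKV3-2 and IGKV5-39 with 2 cells each. IGKJ1 and IGKJ2 were joined in 10 and 9 kappa chains, or 40.0% (21.1 to 61.3%) and 36.0% (18.0 to 57.5%). IGKJ4 was joined in 4 and IGKJ5 in 2. IGKJ3, a J gene that is non-functional in the mouse, was in 0 of 25. All contigs were productive, so that zero is not a measurement. On the heavy chain IGHJ2 and IGHJ3 each gave 9 of 28 chains, or 32.1% (15.9 to 52.4%), IGHJ4 gave 8 and IGHJ1 gave 2.

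The heavy CDR3, the loop that differs most between B cells, had a median length of 14 amino acids with a range of 7 to 20 over 28 cells. The shortest were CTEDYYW on IGHV6-3 and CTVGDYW on IGHV13-2, and the longest was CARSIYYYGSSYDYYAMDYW on IGHV1-75. The 26 unswitched chains also had a median of 14, and the 2 IgG chains had 14 and 15 amino acids. All 32 light chains had a CDR3 of 11 amino acids.

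Light contigs rested on more UMIs than heavy contigs. The UMIs are those of the receptor library, and no expression library was used to measure mRNA. Heavy contigs had a median of 12 UMIs (range 1 to 58) and light contigs a median of 31.5 (range 6 to 272). In the 27 cells with both chains, 24 had more light than heavy UMIs, with a median of 2.27 light UMIs per heavy UMI. IgM contigs had a median of 13 UMIs (range 1 to 58, 23 cells) and the 3 IgD contigs a median of 8 (range 2 to 17). The IGHG2C contig had 6 UMIs and the IGHG3 contig 11, both inside the range of the IgM contigs. The highest value, 272 UMIs, belonged to an IGKV5-43 chain of a cell with no heavy contig.

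**Figure D3:**
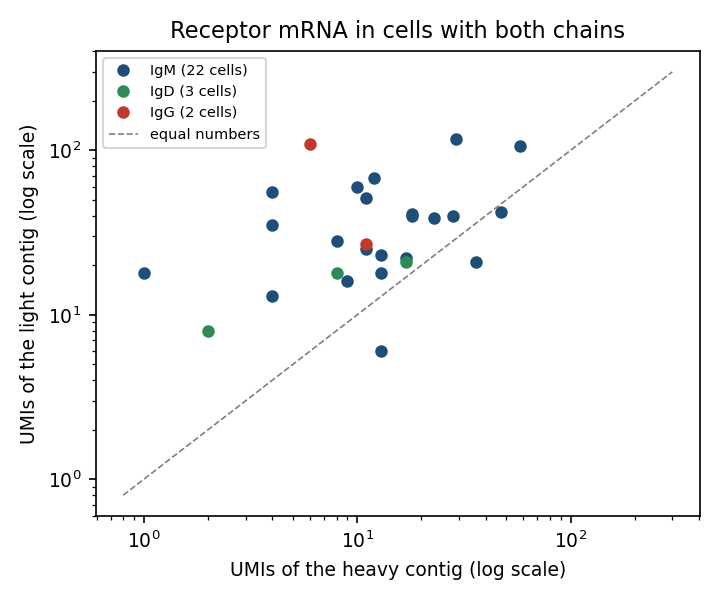
UMIs of the light contig against UMIs of the heavy contig in the 27 cells with both chains, on log axes, coloured by heavy constant region. The dashed line marks equal numbers, and 24 of the 27 cells lay above it. The 2 IgG cells fell among the IgM cells in heavy UMIs.

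Most chains had an unmutated V segment. Of 60 chains, 51 matched their V gene at every base from framework 1 to framework 3, and 9 chains, or 15%, had at least 1 mismatch. The 2 chains of a cell are not independent, so the interval is given by cell. A mismatch in any chain was seen in 6 of 33 cells, or 18.2% (6.98 to 35.5%). Over the library there were 27 mismatches in 16521 bases, or 0.163 per 100 bases. Of IgM heavy chains, 1 of 23 was mismatched, or 4.35% (0.110 to 21.9%), and of IgD heavy chains 1 of 3, by a single base in an IGHV5-16 contig that rested on 2 UMIs. Light chains were mismatched in 5 of 32 cells, or 15.6% (5.28 to 32.8%), among them single bases in an IGLV2 and an IGKV1-110 chain of IgM cells. Both IgG cells had mismatches in both chains. The IGHG2C cell had 1 in IGHV1-59 and 4 in IGKV1-117, and the IGHG3 cell had 1 in IGHV6-3 and 1 in IGKV9-124. Pooled over both chains the IgG cells had 0.629 mismatches per 100 bases, and the unswitched cells 0.142 per 100 bases. A single cell set most of the unswitched value, which was 0.0222 per 100 bases without it. That cell, an IgM cell, had 7 mismatches in IGHV6-6 (chromosome 12, 114434788 to 114435244) and 10 in IGKV10-94 (chromosome 6, 68704508 to 68704978), or 63.0% of all mismatches in the library. With 2 IgG cells in 1 library the difference between switched and unswitched cells was not tested.

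**Figure D4:**
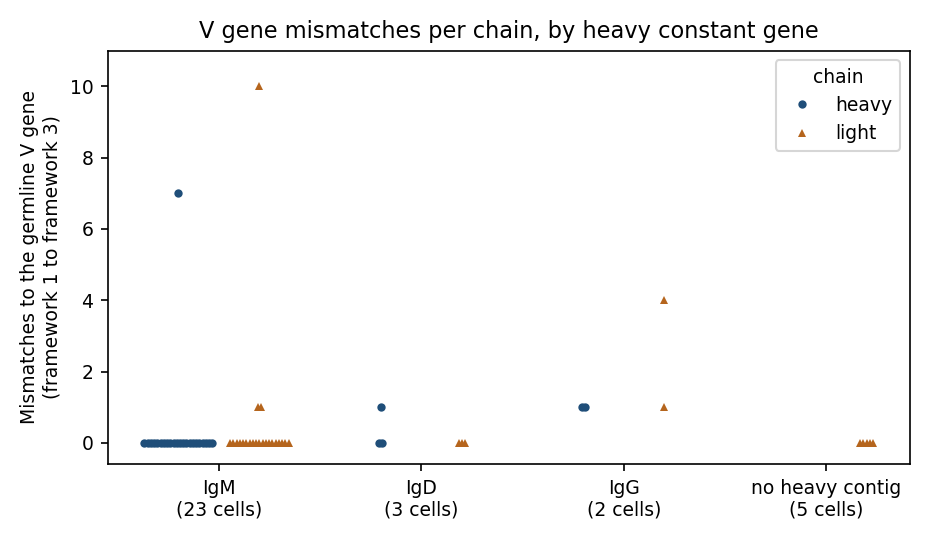
Mismatches to the germline V gene per chain, in bases, for heavy (circles) and light (triangles) chains, by the heavy constant region of the cell. Each point is a chain, spread sideways for visibility. Of the 60 chains 51 lay at 0, and a single IgM cell held the points at 7 and 10.

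No clonal expansion was recorded. The authors' table assigned the 33 cells to 33 clonotypes, so 0 of 33 cells were in a clonotype of 2 or more. Grouping heavy chains by identical V gene, J gene and CDR3 nucleotides also gave 0 of 28 cells. When CDR3s of equal length and at least 80% identity were grouped, 2 of 28 cells, or 7.14%, formed 1 group. A clone shows only when 2 of its cells are sampled, and 5 cells had no heavy chain to match, so these counts put no limit on the share of cells in expanded clones. Both cells were IgM, on IGHV1-9 and IGHJ4, with the heavy CDR3s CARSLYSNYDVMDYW and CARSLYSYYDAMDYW, and both paired them with IGKV1-110, IGKJ1 and the light CDR3 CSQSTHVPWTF.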

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

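The results rest on 1 library with an open tissue label, filtered before deposit, and on 28 heavy and 32 light chains, of which 58 had at least 3 UMIs. The 15 values were recomputed under 9 alternatives fixed before the data were examined. Of 78 recomputed values, 59 equalled the reported one and 19 differed. Apart from the share of cells in expanded clones, for which an interval has no meaning, all 72 lay inside the 95% interval of the reported value. Using contigs whether productive or not, leaving out barcodes with several contigs of a class, and counting clonotypes had nothing to move, since all contigs are productive, no barcode has several of a class and each clonotype is 1 cell. The best-matching V gene and the V part without framework 1 were run for the 2 shares of mismatched chains. The first could not move them, since the named gene was the best match for all 60 chains. The second left both shares as they were and changed 1 chain, IGHV6-6, from 7 to 6 mismatches. A minimum of 3 UMIs removed 2 heavy contigs, lowered the share of cells with both chains from 81.8% to 75.8% and that of mismatched heavy chains from 14.3% to 11.5%, and put IgM at 84.6%. Keeping only cells with both chains put IgM at 81.5%, lambda at 22.2% and mismatched light chains at 18.5%. The definition of a clone alone changed a qualitative result: 0 cells were in expanded clones by the authors' clonotypes, against 7.14% when heavy CDR3s of at least 80% identity were grouped, because the 2 similar IGHV1-9 receptors were then joined. No paired analysis was possible because each group holds 1 library.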

Other observations

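The lambda cells had shorter heavy CDR3s than the kappa cells. In the 6 lambda cells with a heavy chain the median was 9.5 amino acids (range 7 to 14), and in the 21 kappa cells it was 14 (range 7 to 20). Of the 4 IGHV5-17 chains 3 were IgM and 2 were paired with IGLV2, in separate clonotypes with the CDR3s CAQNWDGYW and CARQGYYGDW. The 5 cells without a heavy contig had a median of 48 light UMIs (range 9 to 272), and the 27 cells with both chains had 28 (range 6 to 117). These values were seen in 1 library and were not tested. For the 3 patterns that follow, the tests of UMI support, of CDR1 and CDR2, of the UMI ratio, of heavy CDR3s in IGLV2 cells, of the middle of the CDR3 and of reads per UMI were chosen after the result was seen.

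A single IgM cell held 17 of the 27 V mismatches, 7 in IGHV6-6 and 10 in IGKV10-94, while 51 of the other 58 chains had 0 and none had more than 4. PCR or sequencing error is argued against by the 13 and 18 UMIs behind its chains, the lower of which is 13. A V gene variant or copy absent from the reference was checked by AID hotspots. Of the 17 mismatches, 7, or 41.2% (18.4 to 67.1%), fell in hotspots, which make up 11.6% of the germline bases. Intervals here treat the 17 mismatches as independent draws, but they come from a single cell picked for its mismatches. No other cell used IGHV6-6 or IGKV10-94, so neither gene could be checked in another chain. The hotspot excess is therefore only weak evidence against such a variant or copy. Of the 17, 7 lay in CDR1 or CDR2, which is also 41.2% (18.4 to 67.1%) against 17.9% of the V bases, a margin that its lower bound barely clears. This excess came from IGKV10-94, since in IGHV6-6 only A88G lay in a CDR. The IGHV6-6 mismatches G9A, G117A, C183T, C216T and A234G were silent framework changes. Over both chains, 9 of the 17 replaced an amino acid. Somatic hypermutation of an unswitched cell is thus a hypothesis, and a V gene variant or copy absent from the reference was not excluded. Expression values that could place the cell as a memory or germinal centre cell were not used here.

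IGLV2 chains outnumbered IGLV1 chains by 6 to 1. Free IGLV2 RNA in the droplets is argued against by the UMIs, whose median in IGLV2 contigs was 0.886 times that of kappa contigs (31 and 35). Each IGLV2 chain had at least 6 mismatches to IGLV1 and at most 1 to IGLV2, so none was a miscalled IGLV1 sequence. A chain called IGLV2 by its sequence lies that far from IGLV1 anyway. Whether reads were shared between both genes is therefore not tested by these values. A single expanded clone is argued against by the 5 heavy CDR3s in the 5 IGLV2 cells that had a heavy chain. No biological explanation was tested, and with 7 lambda cells the share of IGLV2 among them spans 42.1 to 99.6%.

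The 2 similar IGHV1-9 and IGKV1-110 receptors matched in 43 of 45 heavy CDR3 bases, or 95.6%, against at most 73.8% in the other 46 pairs of equal length (median 51.7%, SD 9.57), none of which shared a V gene. Without the 9 bases at the V end and 20 at the J end the pair matched in 15 of 16 bases, or 93.8%. The other 41 pairs had a median of 25.0% (SD 14.7), with the second highest of them at 46.2%. The highest, with different V and J genes, reached 92.3%. The middle of the heavy CDR3 alone therefore does not tell siblings of 1 clone from chance likeness of independent rearrangements. It leaves out the light chain, where the pair shared V gene, J gene and CDR3 and the 92.3% pair had IGKV3-2 and IGKV9-124. Likeness over both chains together was not tested. The pair differed at 3 of the 698 bases compared over both chains, A22T and T32C in the heavy CDR3 and T167C in IGKV1-110 (clonotype 25 first, then 26). At each of the 3, 1 of the 2 cells had a germline base. It was clonotype 25 at A22T (IGHD2-5) and T167C, and clonotype 26 at T32C (IGHJ4). The authors called no D gene for either heavy chain, so the germline base at A22T rests on likeness to IGHD2-5. The barcodes differed at 12 of 16 bases and each of the 4 chains had at least 18 UMIs, but clonotype 25 had only 92 and 42 reads per UMI, the third and second lowest of 60 contigs, against a median of 1191. Index hopping from another library of the same run could give such low values, and it stays open, since no other library was used here; it would place that cell in another sample.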
